A study of Fragaria x ananassa with 6 samples.

How the data were processed

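Messenger RNA was sequenced from the fruit receptacle, the fleshy part of the fruit, of the cultivated strawberry Fragaria x ananassa, cultivar Chandler. The labels define 2 genotypes with 3 libraries each. Control plants carried the empty silencing vector, and FaWRKY71-RNAi plants carried a vector whose hairpin RNA targets a conserved part of the coding sequence of the WRKY transcription factor gene FaWRKY71. No plant was treated. Per the labels' protocols, RNA came from independent biological replicates, libraries were made by poly(A) selection with a strand-specific kit, and read pairs of 100 bases were sequenced. The stage of the fruit, the number of transgenic lines and any sequencing batch are not given in the sources used here.

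The authors deposited 1 table of estimated counts, with 28588 IDs in rows and 6 libraries in columns. Per the values in the deposited table, between 80.8% and 85.2% of the counts above 0 in a library are whole numbers (within 1e-09) and the rest are fractions, as can arise when a read that matches several IDs is divided between them. Scaling between libraries would leave few whole numbers, so none was visible. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, nor whether counting used the strand. The IDs are made of FvH4, a series number with or without the letter c before it, a gene number and a suffix. The octoploid strawberry has several near-identical copies of most genes, and 1 ID may collect reads from more than one of them. Column names were matched to samples through the library names in the labels. The replicate number of each control column, but not its genotype, is uncertain, because a column name also resembles the title of another control. All 6 value columns were used.

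The reference table used here lists 77630 genes of another strawberry assembly, and 0 of the 28588 IDs matched it. The IDs therefore have no gene names here. The 30 gene lists fixed in advance (hormone, drought, ripening, defence and tissue markers, WRKY genes among them) select on gene descriptions, so the list tests and the level of FaWRKY71 itself were not analysed here. The naming rule, fixed before the data were examined, has a form for this case: the 2 IDs that rose most and the 2 that fell most among IDs past the threshold, with a mean of at least 5 CPM (counts per 1000000 of the scaled library size) and no overlap between the libraries of the genotypes.

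Estimated counts were rounded to whole numbers. IDs with low counts were removed with filterByExpr, libraries were scaled by the trimmed mean of M-values (TMM), and the genotypes were compared with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood F test, genotype as the only term, all 6 libraries). IDs with a Benjamini-Hochberg adjusted p below 0.05 were called. CPM values use the TMM-scaled library size. Where a genotype had no counts over its 3 libraries, a fold was computed against a floor of 3 counts over the group and is a lower bound; where it had 1 to 3 counts, the ratio has an exact 95% interval. Both pool the 3 libraries of a genotype, so they cover counting error only and not the spread between libraries. Reads without molecular identifiers are not independent molecules, so even the counting error may be larger. Values of single libraries were compared with two-sided exact permutation tests, for which 3 libraries against 3 allow no p below 0.1. Spread within a genotype is the biological coefficient of variation, the spread between libraries beyond counting noise, from edgeR.

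Depth was similar across libraries, from 8385218 to 10000538 counts, and 3 counts correspond to between 0.299 and 0.341 CPM. The test was checked on simulated data in 5 runs. In each run 200 of the 15547 IDs were changed. Values were drawn with the spread of each genotype, fitted as a trend over abundance, so IDs of equal abundance had equal spread. Over the runs, it called 86.1% of the 316 IDs changed 4-fold that passed the filter on the simulated counts, 33.2% of the 331 changed 2-fold and 3.69% of the 325 changed 1.5-fold, and 0.756% of its calls were false. When each ID was instead given its own fitted spread, 90.3% of 309, 43.8% of 329 and 6.04% of 331 were called and 10.3% of the calls were false. Far more IDs were called in the real data (8435). The adjusted p is stricter where few IDs change, and neither simulation let the spread vary both by genotype and by ID. These shares therefore give neither the recovery nor the share of false calls in the real data.

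Alternatives were other scalings (median-of-ratios, upper-quartile, library size alone), DESeq2 1.42.0, limma 3.58.1 (voom), no filter or a stricter filter (1 CPM in 3 libraries and a mean of 50 counts), the replicate number as a block, each library left out in turn, and stricter thresholds. Restricting the test to IDs with whole values and voom with a weight per genotype were chosen after seeing the data. The groups of IDs by abundance and by series were also chosen after seeing the data. The labels number the libraries 1 to 3 in both genotypes without saying that a number marks a shared plant or day.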

Results

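The series measured transcript abundance in receptacles of untreated strawberry plants. The plants carried either a vector whose hairpin RNA targets the transcription factor gene FaWRKY71 or the empty vector. The study as a whole concerned the part of FaWRKY71 in the response of the fruit to drought, and these libraries address which transcripts differ between the genotypes without such stress. The Control libraries held 10000538, 9574751 and 9320022 counts and the FaWRKY71-RNAi libraries 9498057, 8385218 and 8905429. Of the 28588 IDs, 4880 had no count in any library and 15547 passed the filter on low counts. Neither the count table nor the reference used here pairs the IDs with gene names. Results are therefore given by ID and by group of IDs. Whether and how far FaWRKY71 itself was silenced was not analysed here.

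The receptacle transcriptomes of the genotypes differed widely. Of the 15547 IDs tested, 8435 (54.3%) differed between the genotypes by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. In the FaWRKY71-RNAi libraries 4676 were higher and 3759 were lower. The IDs that rose had a median fold of 2.25 and those that fell a median fold of 1.76. A change of at least 2-fold was found for 2797 of the higher and 1444 of the lower IDs, of at least 8-fold for 395 and 201, and of at least 32-fold for 77 and 64. These are fitted folds, whose size depends on the test's prior count where a genotype had no reads. The 3 libraries of one genotype lay entirely above those of the other for 10063 IDs (64.7%). Chance would give 10% on average if all libraries had equal spread. The spread was 6.57% in the controls and 26.7% in the FaWRKY71-RNAi libraries, so 10% is not an exact reference, and the excess was not tested. Among the 8435 called IDs the genotypes did not overlap for 8408, which a call with 3 libraries per genotype nearly requires. Fruit stage, transgenic line and sequencing batch are not given in the sources used here, and any difference between the groups in these cannot be separated from genotype in these counts. The split between higher and lower depended on the scaling: upper-quartile factors gave 48.2% higher and library size alone 65.7%, against 55.4% with TMM, because these scalings moved the median log2 fold change of all IDs by -0.10 and 0.15.

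**Figure D1:**
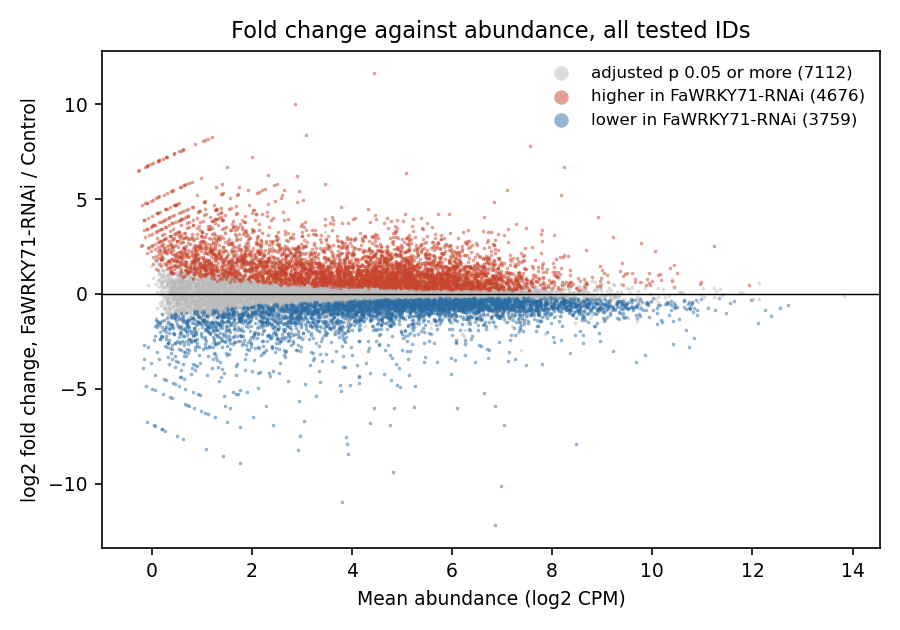
Each point is 1 of the 15547 tested IDs, with its mean abundance in log2 CPM on the horizontal axis and its log2 fold change, FaWRKY71-RNAi over Control, on the vertical axis. Red points (4676) were higher and blue points (3759) lower at an adjusted p of 0.05, and at the highest abundances blue points outnumber red ones.

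The direction of change differed with abundance. Among the 3110 most abundant IDs, those with a mean of at least 67.8 CPM, 739 rose and 1231 fell, whereas among the 3110 least abundant ones 896 rose and 504 fell. Of the 100 most abundant IDs, each with a mean of at least 1010 CPM, 14 rose and 58 fell, with a median log2 fold change of -0.43. The excess of lower calls among these 100 was found with every scaling (17 higher and 49 lower with library size alone), but among the 3110 most abundant it was nearly lost with library size alone (893 higher and 912 lower). The FaWRKY71-RNAi libraries also spread their counts over more IDs. At an equal depth of 8385186 counts, 20468 ± 184 IDs had a count in the FaWRKY71-RNAi libraries and 19568 ± 59.6 in the controls (mean ± SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that this design allows). The 10 most abundant IDs of a library took 5.67% ± 0.64 of its counts in the FaWRKY71-RNAi libraries and 6.49% ± 0.01 in the controls (SD, n = 3, exact permutation p = 0.1). Of the values above 0, 81.4% ± 0.49 were whole in the FaWRKY71-RNAi libraries and 85.1% ± 0.11 in the controls (SD, n = 3). How far fractional counts account for the larger number of IDs in the FaWRKY71-RNAi libraries was not tested.

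At the extremes, transcripts were found in one genotype and hardly or not at all in the other. FvH4_6g38920.1 had 2137, 2161 and 2004 counts in the controls and 0, 0 and 1 in the FaWRKY71-RNAi libraries, that is 230.1 ± 6.44 CPM against 0.036 ± 0.062 (SD, n = 3). The ratio was 6477 with a 95% exact interval from 1162 to 255800, and the adjusted p from edgeR was 3.4e-06. The size of this ratio rests on the 1 count in FaWRKY71-RNAi replicate 3, without which the fitted log2 fold change was -14.06 against -12.20 with all libraries (adjusted p = 0.00012). FvH4_1g10500.1 had 27.5 ± 2.05 CPM in the controls (SD, n = 3) and no count in any FaWRKY71-RNAi library, which makes it at least 258-fold lower (edgeR adjusted p = 2.3e-05). In the opposite direction, FvH4_1g26490.1 had no count in the controls and 42.8 ± 19.4 CPM in the FaWRKY71-RNAi libraries (SD, n = 3), at least 384.7-fold higher (edgeR adjusted p = 0.0020). FvH4_2g31410.1 was at 14.0 ± 3.10 CPM in the FaWRKY71-RNAi libraries (SD, n = 3) and at 0 in the controls after rounding, at least 128.8-fold higher (edgeR adjusted p = 0.00014). Without FaWRKY71-RNAi replicate 2, the edgeR adjusted p of FvH4_1g26490.1 was 0.13 and its call ended, while its fitted log2 fold change was 11.57 against 11.63 with all libraries. The deposited counts of FvH4_1g10500.1, FvH4_1g26490.1 and FvH4_2g31410.1 are not whole. How the fractions arose was not tested, and reads shared with other IDs would make these levels uncertain.

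**Figure D2:**
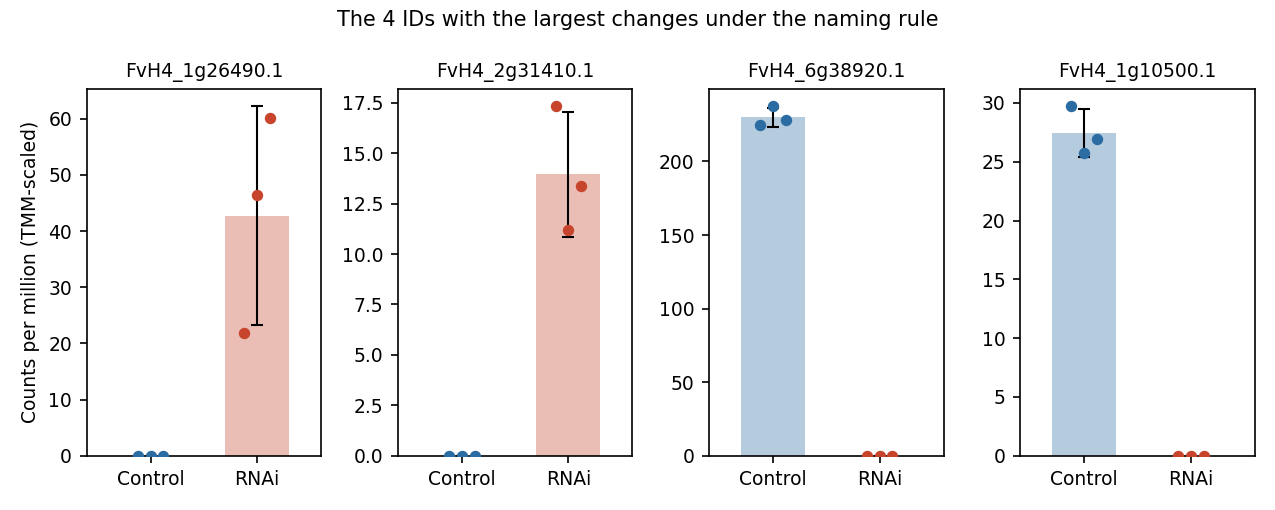
CPM values, scaled by TMM, of the 4 IDs (vertical axis) named under the rule fixed in advance, 1 panel per ID, each with its own vertical axis from 0. Points are the 3 libraries of each genotype (RNAi stands for FaWRKY71-RNAi), bars their mean and error bars the SD, and in every panel the libraries of one genotype lie at or near 0.

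Near-complete presence in a single genotype was not limited to the IDs named above. With at least 20 counts in each library of one genotype and at most 3 counts over the 3 libraries of the other, 25 IDs were found in the controls alone and 26 in the FaWRKY71-RNAi libraries alone. With at least 100 counts in each library these were 7 and 2 IDs.

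The genotypes separated along the first principal component of log2 CPM, which held 78.5% of the variance. The controls lay close together, with a biological coefficient of variation of 6.57%, while that of the FaWRKY71-RNAi libraries was 26.7%. The closest pair of controls, replicates 1 and 2, had a chi-square per degree of freedom of 1.90 over 14854 IDs, where counting noise alone gives about 1. The biological coefficient of variation of this pair was 3.51%. The libraries were counted as separate samples, as labelled, although repeat libraries of 1 RNA would also differ by more than counting noise. The library names carry 1 shared number per genotype, whose meaning is not given in the sources used here. If it marks a single source, the edgeR p-values measure spread within that source and not between plants or lines. FaWRKY71-RNAi replicates 1 and 3 differed least from each other (17.2%), and replicate 2 stood apart from replicate 1 (37.3%) more than from replicate 3 (21.9%). Between genotypes the value for a pair of libraries ranged from 50.8% to 61.3%, above every pair within a genotype. Against the controls, FaWRKY71-RNAi replicate 1 was at 60.1% to 61.3%, replicate 3 at 52.7% to 53.2% and replicate 2 at 50.8% to 50.9%. Without FaWRKY71-RNAi replicate 2, 10241 IDs were called.

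**Figure D3:**
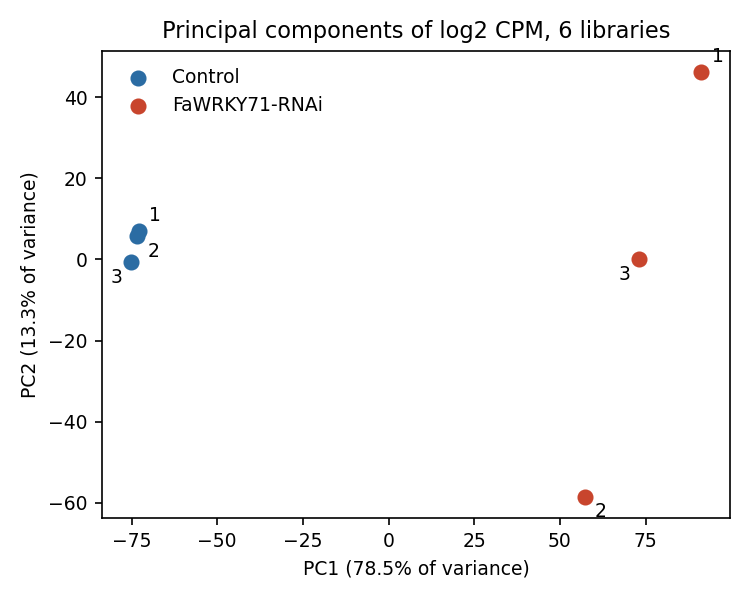
First and second principal components of log2 CPM over the tested IDs, with 78.5% and 13.3% of the variance. Each point is a library, numbered by replicate and coloured by genotype; the 3 controls nearly coincide, and FaWRKY71-RNAi replicates 1 and 2 lie at opposite ends of the second component.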

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

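The count of 8435 called IDs stayed within 1.5 times under every alternative that kept the threshold: from 6302 over IDs with whole values (chosen after seeing the data) and 6522 with the stricter filter, which test fewer IDs, to 8765 with no filter, 8482 with DESeq2, and from 6823 (without FaWRKY71-RNAi replicate 3) to 10241 (without FaWRKY71-RNAi replicate 2) when a library was left out. No ID called in both the main test and one of these alternatives changed direction, and DESeq2 shared 7675 of the calls. Requiring a change of at least 2-fold left 4241 IDs, 2797 higher and 1444 lower, so that 65.95% were higher. An adjusted p below 0.01 left 5878 IDs, 3497 higher and 2381 lower (59.5% higher). The share of calls that were higher was 48.2% with upper-quartile factors, which turned the balance towards lower calls, and 65.7% with library size alone. All 4 named IDs kept their direction in each alternative that tested them, and FvH4_1g26490.1 lost its call without FaWRKY71-RNAi replicate 2 (adjusted p = 0.13) with a log2 fold change of 11.57 against 11.63; why was not tested.

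No pairing by replicate number was seen: deviations from the genotype means correlated at 0.09, -0.04 and 0.03 for libraries with the same number. The controls differed little from each other, so small correlations cannot exclude a pairing. The numbers of the control columns are uncertain. Over all pairs of a control and a FaWRKY71-RNAi library the correlations ranged from -0.133 to 0.111. With the replicate block, which depends on these numbers, 7611 IDs were called. Tests planned for the gene lists and for WRKY71 were not run, because the IDs have no descriptions here. In simulations at this depth with 200 changed IDs per run, 33.2% of 2-fold changes were recovered with a spread per genotype and 43.8% with a spread per ID. Of the calls, 0.756% were false with a spread per genotype and 10.3% with a spread per ID. Neither simulation let the spread vary both by genotype and by ID. With so few changed IDs the adjusted p is stricter than in the real data, where 8435 IDs were called. These shares therefore give neither the recovery nor the share of false calls in the real data. The effect of depth alone was not tested.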

Other observations

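The tests in this part were chosen, or their predictions written, after the data were seen. The IDs carry a series number, and those of the c1 and c3 series fell together. All 27 tested c1 IDs and 9 of the 10 tested c3 IDs were lower in the FaWRKY71-RNAi libraries by edgeR's adjusted p, and 0 were higher. Together these 37 IDs held 411.6 ± 47.3 CPM in the controls and 33.6 ± 11.5 in the FaWRKY71-RNAi libraries (SD, n = 3), 12.3-fold less. Most members were low: their median was 3.48, 4.06 and 4.66 CPM in controls 1 to 3. In FaWRKY71-RNAi replicates 1 to 3 it was 0.40, 0.79 and 0.54 CPM, where 3 counts correspond to 0.299 to 0.34 CPM. The fold of a typical member therefore rests on few counts in the FaWRKY71-RNAi libraries. The 7 numbered series without a letter had median log2 fold changes between -0.03 and 0.11. The 14 tested IDs of the other c series did not fall as a group, with a median of 0.42, 3 higher and 1 lower. Against all other IDs, camera gave adjusted p = 1.5e-11 for c1 and 0.00013 for c3 with a preset correlation between IDs, and adjusted p = 0.16 for both with an estimated correlation. What the c1 and c3 series stand for is not given in the sources used here.

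Reads split between similar IDs can leave fractional counts, and IDs with such counts do not account for the fall of the c1 and c3 series as a whole. The 33 members with whole values in all 6 libraries had a median log2 fold change of -3.67, against -3.56 for all 37. Nor did the fall come from a single library, since the smallest median difference from the control mean among the FaWRKY71-RNAi libraries was -2.68 on the log2 scale. A difference in RNA selection between library preparations and a difference between the plants themselves were not tested.

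The FaWRKY71-RNAi libraries varied more than the controls, and 2 simple accounts of this were tested. FaWRKY71-RNAi replicate 2 alone is argued against, because replicates 1 and 3 differed by 17.2% while the most different pair of controls differed by 7.90%. Split reads that leave fractional counts are argued against, because over IDs with whole values the FaWRKY71-RNAi libraries varied by 25.6% and the controls by 5.89%. Shared reads assigned whole to a single ID would leave whole values, so this comparison does not cover them. Whether control RNA came from more alike fruits than FaWRKY71-RNAi RNA stays open, as does a difference between transgenic lines.

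IDs next to each other in the table changed alike slightly more than by chance. Across 9511 neighbouring pairs, Spearman's rho of the log2 fold changes was 0.083, and none of 1000 permutations exceeded 0.031 in size (permutation p = 0.001, the smallest they can give). Over the 6035 pairs of IDs with whole values rho was 0.0661. IDs are not independent replicates, and the correlation is small.

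The number of called IDs was set against other splits of the libraries. Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 split, gave 8435 calls, and the highest of the others gave 0 by edgeR's adjusted p, with between 4 and 223 IDs at an unadjusted p below 0.05; no other tool was run on these splits. With 10 splits a share under 0.05 cannot be reached. Each of the other splits also mixed the genotypes, so the difference between genotypes counted as spread within a group and reduced the calls. The splits therefore cannot tell whether chance gave the 8435 calls.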
